A study of Mus musculus with 8 samples.

How the data were processed

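Total RNA from dissected renal cortex of 10-week-old male C57Bl6J mice was measured on 1-colour Affymetrix arrays, 1 array per labelled sample. The labels name 4 mice without SPAK, the kinase encoded by Stk39, and 4 wild-type littermates. Both groups ate feed with 0.32% NaCl and 1% KCl, and 6 µg of RNA was labelled per sample, per the labels' protocols. The samples are called WT 1 to 4 and SPAK KO 1 to 4 after the numbers in their titles.

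The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, normalizes arrays to each other and summarises the probes of a probe set. The software version, the genome build and the filter settings were not given in the sources used here. The table held 35556 probe sets on 8 arrays with 0 missing values. The array medians lay between 6.13 and 6.19 in WT and between 6.09 and 6.12 in SPAK KO, so they did not overlap. No detection call or background level comes with such values, so a dim probe set has no stated floor. The number of separate RNA samples, rather than of arrays, limits the precision of the comparison of genotypes.

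Probe sets were named from the platform annotation. Exactly 1 gene symbol was given for 21789 of them, several symbols for 1621 and none for 12146. Only the first kind was named, and for each of 19938 genes the probe set with the highest mean over all arrays was used. Of these genes, 19856 had a place in the RefSeq gene table of GRCm38.p6, which served only for symbols and for neighbours of Stk39. Since no build is named for the values, no coordinates are given.

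Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend or robust options) on the log2 values as deposited, with genotype as the only term over all 8 arrays. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Values given as log2 differences are SPAK KO minus WT, with the moderated standard error (SE). The robust alternative used statmod 1.5.0.

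Gene lists were fixed before the data were examined, 25 in all. They cover cell types (early distal convoluted tubule, late distal and connecting tubule, principal cell, intercalated cells of all types and of type B, thick ascending limb, proximal tubule, podocyte, endothelium, stroma and smooth muscle, immune cell, red blood cell, medulla, adrenal gland, perirenal fat) and processes (the WNK and SPAK kinase pathway, renal sodium transport, aldosterone and glucocorticoid response, renin and macula densa, calcium and magnesium handling, metabolism of glutamine, ammonia and 2-oxoglutarate, cell cycle, Notch signalling, tubular injury, circadian clock). Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists. Camera with an estimated correlation and fry stand beside it. Each list's median was also set against the medians of 10000 random lists, matched gene by gene within 20 bins of mean value. Such lists treat genes as independent and hold no spread between animals. Members were also counted with p-values adjusted over the list alone. A further 4 lists were written after the 60 genes with the smallest p had been seen: immediate early genes, hypoxia response, genes higher in male mouse kidney and genes higher in female mouse kidney. They were adjusted among themselves.

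Genes to be named were chosen by a rule set before the data were examined. It took Stk39, the 10 largest differences in each direction among called genes whose groups did not overlap (unnamed loci skipped), up to 4 members of each list that passed over the list alone or else its 2 members with the smallest p, and 17 genes fixed for the study question. Ren1, 1 of those, was not measured by a probe set with a single symbol and is not analysed here. Any other gene named was chosen after its values were seen. Genes within 20 Mb of Stk39 were compared with all others by a two-sided Fisher's exact test at an unadjusted p under 0.01, since a knockout can carry flanking DNA of another strain.

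Before groups were averaged, every pair of arrays was compared over the 6297 genes with a mean above 8, by the number of genes that differed by more than 0.4 on the log2 scale after the median difference was removed. The SPAK KO arrays, and WT 2 with WT 3, differed far less than the other pairs. For that reason WT means ± SD count WT 2 and WT 3 as 1 sample (n = 3), and SPAK KO levels are given as the mean or range of the 4 arrays with no SD between animals. The fit over 8 arrays remained the primary test, as set beforehand. A limma fit in which arrays that agree were counted once (3 WT samples and 1 SPAK KO sample, the latter assumed to vary like WT) was added after seeing the data. It is printed for Stk39 (the difference only), for the counts with the smallest adjusted p, and among the settings and scores of lists. The SE and adjusted p of other named genes come from the 8-array fit alone and do not hold for the fit counted once.

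Alternatives set beforehand were a block for the replicate number, quantile normalization again, centring each array on its median, leaving out dim probe sets (by their rank, or by a mean under 6), the mean of a gene's probe sets, testing every probe set, a trend with robust variance, array weights, an adjusted p under 0.10, a fold of at least 1.5, leaving out genes near Stk39, and leaving out each array in turn. Cyclic loess and the fits with WT 2 and WT 3 averaged or agreeing arrays counted once came later.

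The gene fit and the list test were tested on simulated data drawn from the means and spreads of the 19938 genes. For SPAK KO against WT, 98 of 100 genes changed by 0.5 on the log2 scale and 100 of 100 changed by 1 were recovered, and 5.96% of the 218 calls were false. A list shifted by 0.3 was the only list of 25 to pass. These data were drawn as 8 separate samples with independent genes. They therefore test neither repeat arrays nor lists whose genes vary together. In a second simulation without any genotype effect, 1 SPAK KO RNA was placed on 4 arrays and 3 WT samples on the others, as the agreement of the arrays would have it. The 8-array fit then called 484.2 genes on average in 20 runs (range 383 to 583), against 0.15 when all 8 samples were separate.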

Results

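Gene expression was measured in the renal cortex of mice lacking SPAK, the kinase that phosphorylates the thiazide-sensitive NaCl cotransporter of the distal convoluted tubule, and of wild-type littermates, with 4 arrays per genotype. According to its stated design, the study asked which genes might act together to limit salt loss by the kidney once SPAK is missing. The values were log2 RMA expression values of 19938 genes.

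Stk39, the disrupted gene, was lower on all 4 SPAK KO arrays. Its log2 values were 8.36, 8.51, 8.60 and 8.11 on WT arrays 1 to 4 and 7.21, 6.98, 6.79 and 7.10 on SPAK KO arrays 1 to 4 (probe set 10483381). The difference was −1.38 ± 0.11 (SE, 8 arrays; limma adjusted p = 5.8e-04). The labels do not say which part of the gene was disrupted, so a residual signal neither checks nor contradicts them beyond this drop. With arrays that agree counted once, the difference was −1.32. That fit holds 1 SPAK KO sample, so it gives the size of the drop but no test of it.

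The arrays of a group did not all agree equally closely. Among 6297 genes with a mean above 8, between 1 and 10 differed by more than 0.4 on the log2 scale in the 6 pairs of SPAK KO arrays, and 3 differed between WT 2 and WT 3. In the 5 other WT pairs the number was 119 to 228. Some genes that differed widely between WT arrays differed little between SPAK KO arrays. Ces1g, a liver-type carboxylesterase, read 6.40, 9.44, 9.51 and 9.22 on the WT arrays and 8.15, 8.09, 8.11 and 8.13 on the SPAK KO arrays. Pdk4, an inhibitor of pyruvate oxidation that responds to fasting, read 8.87, 7.13, 7.32 and 6.92 against 8.69, 8.55, 8.59 and 8.58. For Pdk4, the value of 7.13 on WT 2 lay about as near to 6.92, on another WT array, as to 7.32 on WT 3. The Pdk4 values therefore did not set WT 2 and WT 3 apart from every other WT pair. Both genes were chosen after their values were seen. The labels describe 8 mice. WT 2 and WT 3 were counted as 1 sample in means and SD, and p-values of the 8-array fit measure a spread that, for the SPAK KO arrays, was similar to that between WT 2 and WT 3.

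**Figure D1:**
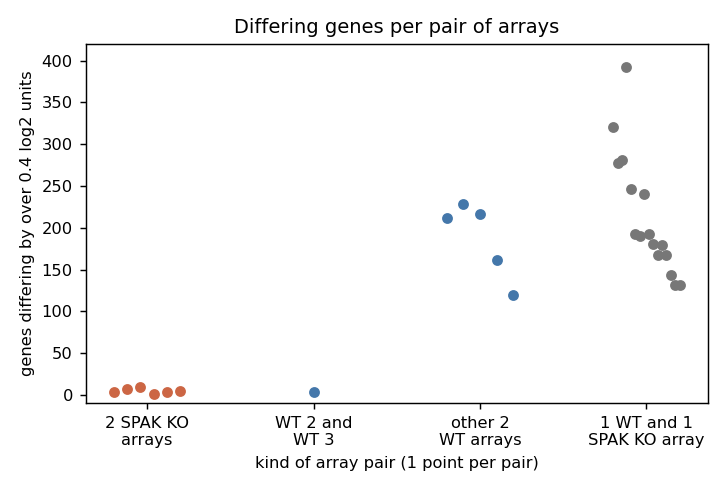
The number of genes, of 6297 with a mean above 8, that differed by over 0.4 log2 units is plotted for each pair of arrays, with 1 point per pair and pairs grouped by kind along the x axis. Pairs of SPAK KO arrays lie at 1 to 10 genes and WT 2 with WT 3 at 3, against 119 to 228 for the other WT pairs and 131 to 393 between genotypes.

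Over the 8 arrays, 278 genes were higher and 136 lower in SPAK KO (limma, Benjamini-Hochberg adjusted p under 0.05), most by little: the median size among the calls was 0.38, or 1.30-fold, and 11 genes were higher and 3 lower by at least 2-fold. Ceacam2, a cell adhesion molecule, had the largest difference, 2.14 ± 0.07 (4.41-fold, adjusted p = 6.0e-07), with 6.94 ± 0.15 in WT (SD, n = 3) and 8.99 to 9.10 on the SPAK KO arrays. Serpina1d, a protease inhibitor, was higher by 1.502 ± 0.16, the amino acid transporter gene Slc7a12 by 1.33 ± 0.13 and Scd1, a fatty acid desaturase, by 1.28 ± 0.10. Id1, Plk3 and Nfkbia, genes that respond quickly to growth factors, stress or NF-κB, were higher by 1.33 ± 0.16, 1.31 ± 0.18 and 1.16 ± 0.10. Rdh16f2, Mogat2 and Tmem252 completed the 10 largest increases with 1.23 ± 0.14, 1.08 ± 0.20 and 1.03 ± 0.09.

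Stk39 was followed among the lower genes by Pvalb, the calcium-binding protein parvalbumin of the early distal convoluted tubule, at −1.30 ± 0.09 (adjusted p = 3.5e-04). Its level was 8.39 ± 0.20 in WT (SD, n = 3) and 7.03 to 7.27 on the SPAK KO arrays. Angptl7, a secreted angiopoietin-like protein, was lower at −1.20 ± 0.22, and Hsd11b1, which regenerates active glucocorticoid, at −0.80 ± 0.08. Rnf180, Nt5dc2, Tstd2, Smcp and the fatty acid hydroxylase gene Cyp4a12a lay between −0.73 and −0.64. Trpm6, the magnesium channel of the distal convoluted tubule, closed the 10 with −0.63 ± 0.10. Of these 20 genes, Mogat2, Angptl7 and Nt5dc2 passed in only 2 of the 8 fits that left out 1 array, and the other 17 passed in each. Ceacam2, Serpina1d, Rdh16f2 and Cyp4a12a have close relatives whose transcripts could bind the same probes, so their identity is less certain than that of the others.

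The counts rested on how the arrays were counted. With arrays that agree counted once, limma called 0 genes, 618 had an unadjusted p under 0.05 where chance gives 997, and the smallest adjusted p was 0.0583, for Ceacam2. With only WT 2 and WT 3 averaged, 175 genes were higher and 78 lower. Leaving out SPAK KO 1, 2, 3 or 4 left 106, 137, 130 or 113 higher and 50, 60, 58 or 51 lower genes. Leaving out WT 2 or WT 3 left 125 or 174 higher and 57 or 77 lower genes, and without WT 4 there were 407 and 218. Centring each array on its median changed the split to 673 higher and 88 lower, 88.4% higher instead of 67.1%.

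**Figure D2:**
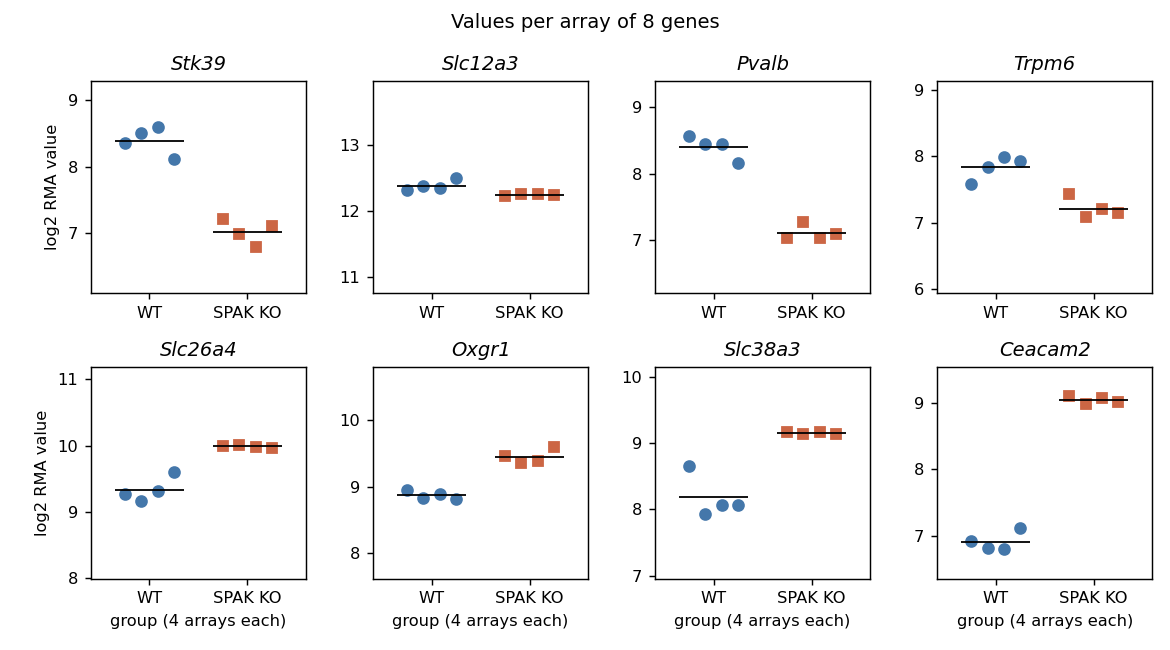
Log2 RMA values per array of 8 genes are drawn for WT (circles) and SPAK KO (squares), with 1 panel per gene, the same span on each y axis and a line at the mean of 4 arrays. SPAK KO arrays lie below WT for Stk39, Pvalb and Trpm6 and above WT for Slc26a4, Oxgr1, Slc38a3 and Ceacam2, while Slc12a3 differs by −0.14.

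Early distal convoluted tubule markers did not pass the set test, although Pvalb and Trpm6 were among the genes with the largest decreases. Slc12a3, the NaCl cotransporter that SPAK phosphorylates, differed by −0.14 ± 0.05 (adjusted p = 0.183), from 12.39 ± 0.09 in WT (SD, n = 3) to 12.23 to 12.26 on the SPAK KO arrays. Of 11 early distal convoluted tubule markers, 2 were lower, Pvalb and Trpm6, and 0 higher, with the same 2 adjusted over the list alone. The list's median was −0.07, and 0.23% of its matched random lists had a lower one. The list did not pass camera (adjusted p = 0.101, or 0.406 with an estimated correlation). It passed as lower by fry (adjusted p = 0.0178) and by camera in 4 of 19 settings: with quantile normalization again (0.0074), cyclic loess (0.0070), means under 6 left out (0.0297) and without WT 1 (0.0338). Of 10 late distal and connecting tubule markers, 2 were higher, the calcium-binding protein gene S100g at 0.35 ± 0.06 and Scnn1b, a subunit of the epithelial sodium channel ENaC, at 0.28 ± 0.05. They passed in 3 and 2 of the 8 fits that left out 1 array. Adjusted over the list alone 5 were higher, among them Scnn1a at 0.25 ± 0.06 and Hsd11b2 at 0.19 ± 0.05. That list passed as higher (median 0.13, camera adjusted p = 0.0023; adjusted p = 0.243 with an estimated correlation). Calb1, Scnn1g and Kcnj1 gave −0.21 ± 0.08, 0.05 ± 0.07 and 0.02 ± 0.05 and did not pass, and Kcnj1 fell below 0 with quantile normalization or cyclic loess.

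Of 12 intercalated cell markers of all types, 5 were higher and 0 lower, and 8 were higher adjusted over the list alone. The proton pump subunit genes Atp6v1g3, Atp6v1c2 and Atp6v0d2 gave 0.52 ± 0.07, 0.44 ± 0.07 and 0.36 ± 0.05, and the ammonia channel gene Rhbg gave 0.31 ± 0.05; Atp6v1c2 passed in 5 and Rhbg in 4 of the 8 fits that left out 1 array. Slc4a1 (−0.15) and Atp6v0a4 (−0.03), named after their values were seen, had differences below 0 and did not pass. The list of 12 had a median of 0.31 (camera adjusted p = 1.8e-07; adjusted p = 0.0716 with an estimated correlation). Of 6 genes of type B cells, which secrete bicarbonate, 3 were higher and 4 adjusted over the list alone. Slc26a4, the chloride/bicarbonate exchanger pendrin, was higher by 0.65 ± 0.08 (1.57-fold, adjusted p = 0.0047), from 9.37 ± 0.20 in WT (SD, n = 3) to 9.96 to 10.0 on the SPAK KO arrays. Oxgr1, the receptor for 2-oxoglutarate in these cells, was higher by 0.58 ± 0.06 and the receptor kinase gene Insrr by 0.51 ± 0.10, the latter in only 2 of the 8 fits that left out 1 array. Slc4a9 and Slc4a8, a bicarbonate transporter and the sodium-driven chloride/bicarbonate exchanger, gave 0.31 ± 0.11 and 0.10 ± 0.06 and did not pass. The type B list had a median of 0.41 (camera adjusted p = 4.1e-06; 0.0422 with an estimated correlation).

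Of 9 thick ascending limb genes measured, 2 were higher, Cldn16, a paracellular channel protein for magnesium and calcium, by 0.32 ± 0.05 and the calcium-sensing receptor gene Casr by 0.31 ± 0.06, the latter in 2 of the 8 fits that left out 1 array. Adjusted over the list alone 6 were higher, including Slc12a1, the Na-K-2Cl cotransporter, at 0.24 ± 0.05 and Cldn19 at 0.24 ± 0.05. The list's median was 0.22 (camera adjusted p = 4.1e-06; 0.0422 with an estimated correlation). Of 8 principal cell markers, the water channel genes Aqp4 (−0.35 ± 0.07) and Aqp2 (−0.29 ± 0.06) were lower, each in only 1 of the 8 fits that left out 1 array. Counts adjusted over the list alone were 2 higher, Aqp3 (0.23 ± 0.06) and Gata3 (0.21 ± 0.07), and the same 2 lower. That list did not pass (adjusted p = 0.930), and its median of 0.0035 and mean of −0.03 had opposite signs.

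Among markers of other cells, Aqp1, a proximal tubule water channel, was higher by 0.34 ± 0.06, in 5 of the 8 fits that left out 1 array, with 1 of 17 proximal tubule genes called, or 2 adjusted over the list alone (Slc13a3 0.25 ± 0.06), a list median of 0.04 and camera adjusted p = 0.101. Of 5 podocyte genes 0 were called and 1 was higher adjusted over the list alone (Wt1, 0.17 ± 0.05). That list passed as higher (median 0.11, adjusted p = 0.0181; adjusted p = 0.243 with an estimated correlation), but not in 4 of 19 settings, without WT 2 (0.0516), with dim genes left out by rank (0.0630) or by a mean under 6 (0.0854), or with the mean of all probe sets (0.232). Of 5 perirenal fat markers, Retn was higher by 0.31 ± 0.07, in 0 of the 8 fits that left out 1 array, and 3 were higher adjusted over the list alone (Adipoq 0.29 ± 0.11, Fabp4 0.16 ± 0.06). The fat list also passed (median 0.16, adjusted p = 0.0040; adjusted p = 0.154 with an estimated correlation). That call ended when dim genes were left out, by rank (adjusted p = 0.0630) or by a mean under 6 (0.335), and Retn and Adipoq had means under 6. Of 8 endothelial genes 0 passed either way (median −0.05, adjusted p = 0.534), with Emcn at −0.12 ± 0.05 and Ehd3 at −0.15 ± 0.07. In stroma and smooth muscle 1 of 9 was lower by both adjustments (Fn1, −0.25 ± 0.05; list adjusted p = 0.707) and among immune cell genes 1 of 13 (Cd3e, −0.31 ± 0.06; list adjusted p = 0.706), Fn1 in 0 and Cd3e in 1 of the 8 fits that left out 1 array. The medulla list (7 genes, median −0.04, adjusted p = 0.930, with Slc14a2 lower over the list alone at −0.21 ± 0.05) and the adrenal list (5 genes, median −0.05, adjusted p = 0.215, with Cyp11b1 lower over the list alone at −0.26 ± 0.08) had 0 genes called over all genes. Alas2, the only red blood cell gene measured, gave −0.02 ± 0.10, and the list adjusted p was 0.930. With arrays centred on their median, the proximal tubule list passed with the preset correlation (median 0.10, adjusted p = 0.0477). On the values as deposited, camera with an estimated correlation gave it an adjusted p of 0.363. Centring adds the same amount to every difference. It thereby turned the medians of the endothelium, stroma, immune, medulla and adrenal lists positive, at 0.01, 0.05, 0.05, 0.02 and 0.0069, and these lists did not pass.

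**Figure D3:**
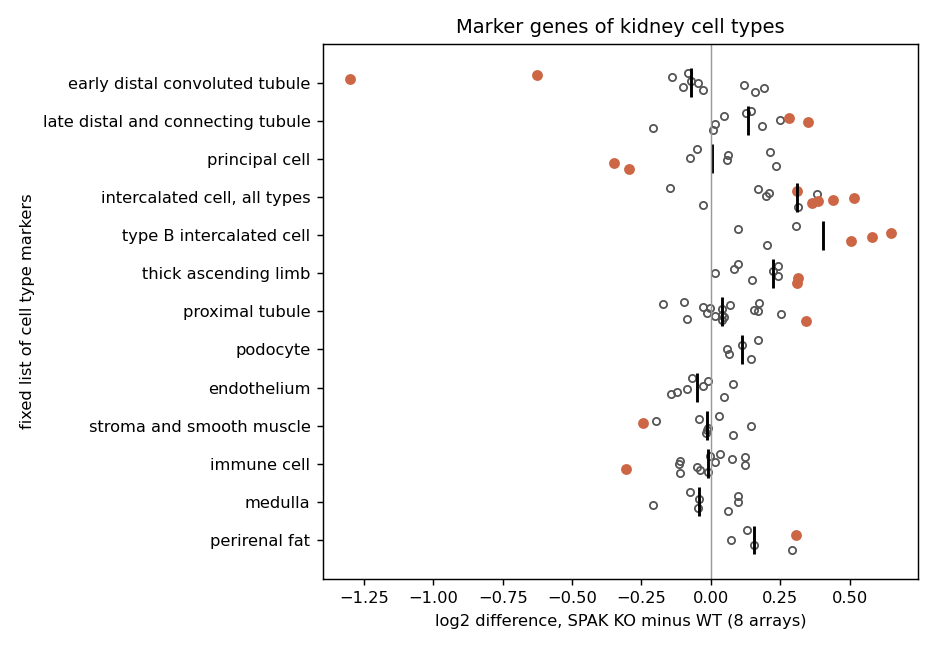
Log2 differences (SPAK KO minus WT, 8 arrays) are plotted for each measured gene of 13 fixed lists of cell type markers, with filled points for genes at adjusted p under 0.05, open points for the others and a bar at each list's median. Medians are 0.31 and 0.41 for the intercalated and type B lists and 0.22 for the thick ascending limb, against −0.05 for endothelium.

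Of 14 renal sodium transport genes, 2 were higher, Slc26a4 and Scnn1b, and 5 adjusted over the list alone (median 0.05, camera adjusted p = 0.0214; adjusted p = 0.249 with an estimated correlation). The sodium transport list did not pass with quantile normalization again (0.0514), cyclic loess (0.0555), or dim genes left out by rank (0.147) or by a mean under 6 (0.243). Of 14 genes of the aldosterone and glucocorticoid response, 2 were higher, Sgk1, a kinase that keeps ENaC at the cell surface, by 0.50 ± 0.09 and the clock gene Per1 by 0.93 ± 0.18, in 4 and 3 of the 8 fits that left out 1 array. As many as 8 were higher adjusted over the list alone, among them Tsc22d3 at 0.42 ± 0.11 and Cnksr3 at 0.21 ± 0.05. As a list they had a median of 0.20 (camera adjusted p = 5.1e-06; 0.0468 with an estimated correlation). Of 15 genes of the WNK and SPAK kinase pathway 0 were called. Adjusted over the list alone, Slc12a1, Sorl1 (0.19 ± 0.06) and Cab39l (0.20 ± 0.07), 3 genes, were higher and 1 gene, Slc12a2, the secretory Na-K-2Cl cotransporter, was lower at −0.28 ± 0.07. The list did not pass (adjusted p = 0.930), and its median of −0.01 (0.05 with arrays centred on their median) went against the upward direction of the test. The kinase genes Oxsr1, Wnk1 and Wnk4 gave −0.02 ± 0.05, −0.01 ± 0.06 and −0.08 ± 0.07, and Oxsr1 and Wnk1 turned positive with arrays centred on their median. A second, dimmer probe set of Wnk1 gave −0.28. Of 6 renin and macula densa genes 0 passed either way (median 0.07, adjusted p = 0.215), with Ptges at 0.15 ± 0.06 and Ptgs2 at 0.13 ± 0.10. Of 18 calcium and magnesium genes, S100g and Casr were higher and Trpm6 lower. Adjusted over the list alone 3 were higher, with Trpv5 at 0.14 ± 0.04, and 1 lower (list median 0.02, adjusted p = 0.309).

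Of 23 genes of glutamine, ammonia and 2-oxoglutarate metabolism, 4 were higher, 0 lower and 19 did not pass. Slc38a3, a glutamine transporter that feeds renal ammonia production, was higher by 0.97 ± 0.13 (1.96-fold, adjusted p = 0.0059), the dicarboxylate transporter gene Slc13a2 by 0.51 ± 0.06, and Oxgr1 and Rhbg as given above, Rhbg in 4 of the 8 fits that left out 1 array. Adjusted over the list alone 7 were higher and 1 lower. The list's median was 0.09 (camera adjusted p = 1.0e-04; 0.0422 with an estimated correlation). Of 13 cell cycle genes, 3 were lower, Ccna2 (−0.43 ± 0.08), Aurka (−0.35 ± 0.08) and Mcm5 (−0.26 ± 0.05), in 4, 1 and 1 of the 8 fits that left out 1 array, and 7 were lower adjusted over the list alone, including Mki67 at −0.35 ± 0.09. That list's median was −0.26 (camera adjusted p = 4.7e-06; adjusted p = 0.154 with an estimated correlation). In Notch signalling, Hes1, a target gene of the pathway, and its ligand Jag1 were higher by 0.47 ± 0.06 and 0.33 ± 0.06 and the ligand Jag2 was lower at −0.36 ± 0.07, among 12 genes and by both adjustments, Jag1 and Jag2 in 4 each of the 8 fits that left out 1 array. The list passed weakly (median 0.06, adjusted p = 0.0414; adjusted p = 0.243 with an estimated correlation), and in 8 of 19 settings, not without WT 2, WT 3, SPAK KO 1 or SPAK KO 3 (0.0984, 0.0815, 0.0647 and 0.0793). Of 8 tubular injury genes 0 were called and 1 was higher adjusted over the list alone (Clu, 0.30 ± 0.07). The list did not pass (adjusted p = 0.706) and its median of −0.01 and mean of 0.02 differed in sign. Of 15 circadian clock genes Per1 was higher, with Nr1d1 (0.27 ± 0.06) added over the list alone to make 2. The clock list did not pass (median 0.07, camera adjusted p = 0.0689, or 0.406 with an estimated correlation). With the preset correlation it passed in 4 of 19 settings: without WT 2 (0.0384) or WT 3 (0.0114), with both averaged (0.0207) and with agreeing arrays counted once. The last of these leaves 1 SPAK KO sample, so it does not test the genotype.

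In all, 11 of the 25 lists passed camera with the preset correlation, 10 as higher and 1 as lower. Some lists share genes, so they are not separate findings. Slc26a4 and Scnn1b, the called sodium transport genes, are also type B and late distal markers. Oxgr1 and Rhbg, of the glutamine list, are also intercalated cell markers. Scnn1a and Hsd11b2 are in both the late distal and the aldosterone lists. With an estimated correlation 4 passed (type B intercalated cell, thick ascending limb, aldosterone and glucocorticoid response, and glutamine, ammonia and 2-oxoglutarate), and by fry 13, with the early distal convoluted tubule and proximal tubule lists besides the 11. In percent of matched random lists with a lower median, Notch signalling lay at 87.8, renal sodium transport at 89.2 and podocyte at 93.5. The other lists past camera with the preset correlation lay at 99.8 or more, or at 0 for the cell cycle. Among lists that did not pass it, the early distal convoluted tubule lay at 0.23, endothelium at 1.58 and the circadian clock at 96.5. With arrays that agree counted once, 1 SPAK KO sample is left. A list test then sets genes against genes and cannot tell the genotype from the state of 1 animal, so nothing is concluded from it.

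Of 334 genes within 20 Mb, 23 (6.89%) had an unadjusted p under 0.01, against 1451 of 19521 (7.43%) elsewhere (odds ratio 0.921, 95% interval 0.573 to 1.41, two-sided Fisher's exact p = 0.833). Within 10 Mb the odds ratio was 1.29 (Fisher's exact p = 0.395). At an adjusted p under 0.05 it was 0.568 within 20 Mb and 1.13 within 10 Mb. The called genes within 20 Mb, Stk39 aside and named after their values were seen, were Agps (−0.57 ± 0.05), Itgb6 (−0.37 ± 0.05) and Gpr155 (−0.37 ± 0.05), which were lower, and Pde1a (0.40 ± 0.08), which was higher.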

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

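The tests on the agreement of arrays, on tubule markers and on sex-biased genes were chosen after the results had been seen, and the counts over other splits of the arrays were planned before.

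Among the named genes, 7 of 164 groups of 4 arrays had 1 array far from the other 3, where chance flags about 8.2 if arrays are independent. All 7 concerned WT 1 or WT 4. Arrays that agree like repeats break that assumption, so the comparison with 8.2 does not measure chance here. WT 1 was apart for Scd1 (9.23, the others 9.69 to 9.70), Rdh16f2 (7.98, the others 8.61 to 8.73), Angptl7 (8.16, the others 9.25 to 9.36) and Aqp3 (9.41, the others 9.60 to 9.61). WT 4 was apart for Aqp4 (5.75, the others 5.48 to 5.50), Slc12a1 (10.8, the others 10.6) and Cyp11b1 (4.43, the others 4.71 to 4.75). Outside the genes tested, 64 of the 12146 probe sets without a symbol passed when every probe set was tested (16 higher, 48 lower), as did 22 of the 1621 with several symbols (18 higher, 4 lower).

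The first pattern is the agreement of the arrays: on the 200 genes that differed most between WT 1 and WT 4, the close pairs of arrays differed by a median of 1.37 times as much as on other genes, against 2.78 to 3.03 times in the 8 pairs of WT 2 or WT 3 with a SPAK KO array, which differ in genotype and did not choose those genes. This is consistent with repeat arrays of 1 RNA, or of a pool, for the 4 SPAK KO arrays and for WT 2 and 3. Scaling of whole arrays by the authors is argued against, since the ranks of genes within arrays, which such scaling leaves as they are, had a WT variance a median of 2.83 times that of SPAK KO; other steps of their processing were not tested. Separate mice in very similar states stay open, as 0 genes differed 2-fold in any close pair and either account allows that. Only 1 of the 35 splits of the arrays, the real one, gave 278 genes in 1 direction and 136 in the other (highest other split 0 and 0), and 1 gave 11 lists (highest other 10), but splits that part arrays which agree like repeats can hardly call a gene, so chance is not excluded, and a single SPAK KO RNA on 4 arrays could give such counts too (484.2 calls on average in the simulation without an effect).

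The second pattern is that the intercalated cell and thick ascending limb lists passed as higher, by some of their genes, although the intercalated list of all types lost its call with an estimated correlation (adjusted p = 0.0716). More medulla in the SPAK KO pieces is argued against for type B cells, which belong to the cortex and whose list had a median of 0.41, but for the thick ascending limb it cannot be told apart, because the medulla list passed in neither direction (median −0.04, camera adjusted p = 0.930) and 5 of its 7 genes were dim, with a mean under 6. A lower share of proximal tubule RNA would raise endothelial and stromal genes alike, whereas the intercalated list lay above them by at least 4.19 SE of the difference of list means. This SE was taken across genes as if they were independent, although the intercalated genes had an estimated correlation of 0.20. It holds no spread between animals, so the difference speaks only for these arrays. The state of a single animal stays open: counted once, SPAK KO lay above the 3 WT samples by 2.77 of their SD in its intercalated score and by 4.98 in its thick ascending limb score, and 3 samples against 1 allow no exact permutation p under 0.25. A response to the loss of SPAK may account for the pattern, but with these arrays it cannot be told apart from such a state.

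The third pattern is that a list of genes higher in male mouse kidney passed as lower and a list of genes higher in female kidney as higher (values are given with the other observations). Female RNA on the SPAK KO arrays is argued against, as the 3 Y-linked genes measured had a median difference of −0.0286 and Xist stayed between 3.75 and 4.03 on all arrays. A lower share of proximal tubule RNA would lower the proximal tubule list, whose mean was 0.06. That mean lay 3.72 SE above the mean of 7 male-type genes outside the list that had not been seen beforehand (−0.13). Cyp4a12a was left out here and below, as its close relative Cyp4a12b had been seen. The distance is overstated, because Slc7a13 (0.18 ± 0.07), which is in both lists, was kept only in the proximal tubule list. Its SE also treats genes as independent and holds no spread between animals, so whether such a share accounts for the pattern is undecided. Lower androgen action may account for it, and members not seen before the lists were written passed weakly for the male-type genes (8 genes, median −0.11, limma camera adjusted p = 0.0418, but unadjusted p = 0.264 by limma with an estimated correlation) but not past the test for the female-type genes (4 genes, adjusted p = 0.135), which leaves it open. The state of 1 animal also stays open, although SPAK KO counted once lay −7.09 and 18.1 SD of the 3 WT samples from them in the male-type and female-type scores, because the lists hold genes chosen from these arrays and 3 samples against 1 allow no exact permutation p under 0.25.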

How the results depend on the processing

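Cyclic loess and both ways of averaging arrays that agree were chosen after seeing the data. Replicate numbers did not pair the arrays: same-numbered WT and SPAK KO arrays had correlations of deviations of −0.05, 0.08, −0.13 and 0.13, 2 of 4 WT arrays correlated best with their own number, and the replicate block gave 129 higher and 45 lower genes. Counts of higher and lower genes moved by over 1.5 times to 673 and 88 with arrays centred on their median, 526 and 241 with a trend and robust variance, 540 and 396 at an adjusted p under 0.10, 61 and 15 at 1.5-fold or more, 175 and 78 with WT 2 and 3 averaged, and 0 and 0 with agreeing arrays counted once. They were 462 and 202 without means under 6, 152 and 101 when every probe set was tested, and 396 and 218 with array weights, where 1 of the 2 counts moved that far. Leaving out each array gave 106 to 407 higher and 50 to 218 lower genes, 10 to 12 lists, and −1.47 to −1.30 for Stk39. Lists past the test fell to 7 without the dimmest genes by rank and to 4 with an estimated correlation. Stk39 was −1.32 with agreeing arrays counted once, a fit with 1 SPAK KO sample that gives no test of it. The odds ratio near Stk39 turned to 1.29 within 10 Mb, or 1.13 at an adjusted p under 0.05. Uncalled genes near 0 changed sign: Alas2 gave 0.0176 (quantile), 0.0337 (median), 0.0105 (loess) and 0.0234 with either averaging, Kcnj1 −0.00611 (quantile) and −0.0131 (loess), and Oxsr1 0.0383 and Wnk1 0.0486 (median). Leaving out each array gave −0.0798 to 0.0424 for Alas2, −0.0181 to 0.0512 for Kcnj1 and −0.0347 to 0.0349 for Wnk1. Centring arrays on their median adds the same amount to every difference, so its sign changes follow from the setting. The median difference of all genes thereby moved from −0.0129 to 0.0457. For the other settings the cause was not tested, except that fewer arrays or genes follow from the setting itself. Of 47 called named genes, 25 passed without each array in turn and 35 with WT 2 and 3 averaged. No detection level comes with the values, so dim genes have no stated background.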

Other observations

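The 4 lists described here were written after the leading genes had been seen, and so were their tests, so their counts are not independent evidence of a direction. Of 30 immediate early genes, which are transcribed within minutes of a stimulus, 12 were higher in SPAK KO (limma adjusted p under 0.05) and 0 lower. Egr1 was higher by 0.91 ± 0.07 (SE, 8 arrays), Fos by 0.73 ± 0.05, Jun by 0.83 ± 0.12 and Zfp36 by 0.97 ± 0.13. The list had a median of 0.13 (camera adjusted p = 7.9e-11; 0.0134 with an estimated correlation). The 24 members not seen beforehand had a median of 0.07 and 6 of them passed, and as a set they passed with the preset correlation (camera adjusted p = 2.8e-04) but not with an estimated correlation (unadjusted p = 0.0780). Of 14 hypoxia response genes 0 were called and 3 were higher adjusted over the list alone, Ddit4 (0.56 ± 0.14), Bnip3 (0.26 ± 0.07) and Slc2a1 (0.19 ± 0.06), with a list median of 0.03 (camera adjusted p = 0.0184, or 0.0461 with an estimated correlation). Only 66.0% of its matched random lists had a lower median.

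Of 14 genes that are higher in male than in female mouse kidney, 7 were lower in SPAK KO and 0 higher. They included the organic anion transporter gene Slco1a1 (−0.62 ± 0.06), Cyp4a12b (−0.61 ± 0.06), Odc1, the first enzyme of polyamine synthesis (−0.48 ± 0.06), Acsm3 (−0.42 ± 0.05) and Gusb (−0.28 ± 0.05). Kap, an androgen-regulated proximal tubule gene, gave 0.02 ± 0.05 and Slc7a13 gave 0.18 ± 0.07, against the direction of the list, and neither was called. Kap had means of 13.69 on the 4 WT and 13.72 on the 4 SPAK KO arrays, where the highest values per array were 14.13 to 14.30. Whether a change would show in full at that level was not tested. Cyp4a12a and Cyp4a12b, both among the 7 lower genes, are close relatives and may not count separately. This list had a median of −0.26 (camera adjusted p = 1.3e-09; 0.0134 with an estimated correlation). Of 8 genes that are higher in female kidney, 4 were higher in SPAK KO, Slc7a12, Rdh16f2, Hao2 (0.65 ± 0.06) and Rdh16 (0.53 ± 0.07), with a list median of 0.38 (camera adjusted p = 6.7e-08; 0.0053 with an estimated correlation). Rdh16f2, as given above, has close relatives that could bind its probes, so Rdh16f2 and Rdh16 may not count separately. All 8 mice are male per the labels.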
